A study of Mus musculus with 13 samples.

How the data were processed

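Chromatin accessibility was measured by bulk Omni-ATAC-seq, in which a transposase inserts adapters into open chromatin, in haematopoietic stem cells (HSCs) of C57BL/6 mice. Per the series description, mice received 1 Vwf+ HSC each and were classed by the blood lineages restored over 16 weeks. Donor-derived Gata1-negative HSCs were then sorted from bone marrow, 500 cells per replicate. Per the labels' protocols, libraries were made with a Nextera DNA kit from cells with the surface phenotype LSK Flt3- CD150+ CD48- CD45.2+. The 13 libraries fall into 4 of multilineage recipients (MUL-HSC), 6 of PEM-restricted recipients (PEM-HSC) and 3 of P-restricted recipients (PLT-HSC).

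The deposited table holds raw counts, whole numbers of reads or fragments per accessible region, for 115295 regions in 13 columns named as the samples. Per the submitters' processing notes, Trim Galore, FastQC, Bowtie2, SAMtools, Picard and MACS2 were used with the mm9 genome. Their versions and settings are not given in the sources used here, and neither are the counting tool, the pooling of libraries for peak calling, the handling of duplicates or any shift of read ends for the transposase. If regions were called mainly in the more deeply sequenced libraries, regions open in few cells of a shallow library would be under-represented. Region ends lay beyond the mm9 length of 0 of 21 chromosomes and beyond the mm10 length of 8 of them. Regions were 199 to 3907 bp wide with a median of 417 bp. Positions are given as in the table, in mm9, and whether starts count from 0 or 1 is not given in the sources used here. No mm9 genome or annotation was used, so regions are named by position, no gene is assigned to them, and the gene lists and sequence motifs chosen before the data were examined were not tested.

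Counts were analysed in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16. Regions were filtered with filterByExpr by group, which left 59408 regions holding 91.4% of all counts. TMM factors scaled the libraries, and all 13 libraries entered 1 robust fit with a coefficient per group, tested two-sided. P-values were adjusted with the Benjamini-Hochberg method over all tested regions and called at 0.05. Standard errors are the fold change divided by the root of the F statistic. The biological coefficient of variation was 15.6%. CPM values use the TMM-scaled totals, and log2 CPM uses a prior count of 2. None of the 13 regions on chromosome Y passed the filter.

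Library totals ranged from 1276962 to 3851165 counts, a ratio of 3.02. On simulated counts with the means and totals of these libraries, the test recovered 33% of regions changed 2-fold and 73% of those changed 4-fold for PLT-HSC against MUL-HSC. It recovered 45% and 83% for PEM-HSC against MUL-HSC, and 34% and 85% for PLT-HSC against PEM-HSC. Unchanged regions called in these simulations numbered 7, 6 and 12 in the same order. Only 100 regions were changed by each fold, fewer than were called in the data for both comparisons with MUL-HSC, so recovery there may differ. For PLT-HSC against PEM-HSC they outnumber the 1 region called. The adjusted threshold is stricter when fewer regions change, so recovery may be lower for that comparison. Counting intervals are exact at the 95% level and cover counting error only, since reads carry no molecular identifiers. The 24 pairs of libraries within groups differed by more than sampling noise, with a chi-square per degree of freedom of 1.48 to 2.51, so no library was counted as a duplicate. The labels do not state that replicates came from separate recipients, so p-values measure only the spread between these samples, which may be technical.

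In each comparison the text names, by a rule fixed before the data were examined, the 5 regions of smallest p in each direction among those past the threshold, or all where fewer passed. The position of PEM-HSC between the other groups used 36 splits. In each, the 100 regions of smallest p per direction were picked in 2 MUL-HSC libraries and 1 or 2 PLT-HSC libraries, then measured in the libraries left over. Fold changes of comparisons sharing the MUL-HSC libraries were set beside 20 simulated data sets with no group difference, and beside splits of the MUL-HSC libraries into pairs. Library similarity is the Spearman correlation of log2 CPM, tested one-sided by 100000 permutations of the group labels. Alternatives were DESeq2 1.42.0, scaling by totals alone, cyclic loess offsets (limma 3.58.1), no filter, a mean of at least 20 counts, a fit of the compared groups alone, the replicate number as a block, 1 surrogate variable (sva 3.50.0), a fit without robust estimation, a fit without chromosomes X and Y, and leaving out each library. After seeing the data, thinning to the smallest total, leaving out libraries under 2000000 counts, the library total or the share of counts in the 5000 strongest regions as a covariate, and all regroupings for the similarity were added.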

Results

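HSCs derived from single transplanted HSCs were compared by the lineages that their recipient had restored. MUL-HSC libraries held 1307222 to 2831520 counts (n = 4), PEM-HSC libraries 1276962 to 3851165 (n = 6) and PLT-HSC libraries 2378024 to 3307889 (n = 3). The 5000 strongest regions took 32.9% to 38.0% of the counts that a library had in tested regions, which is the base of this share throughout. The first principal component of log2 CPM held 24.6% of the variance. MUL-HSC replicates 1, 2 and 4 scored -104, -111 and -55.1 on it and MUL-HSC replicate 3 scored -11.9, whereas PLT-HSC libraries scored 14.8 to 65.2 and PEM-HSC libraries -5.28 to 66.2.

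**Figure D1:**
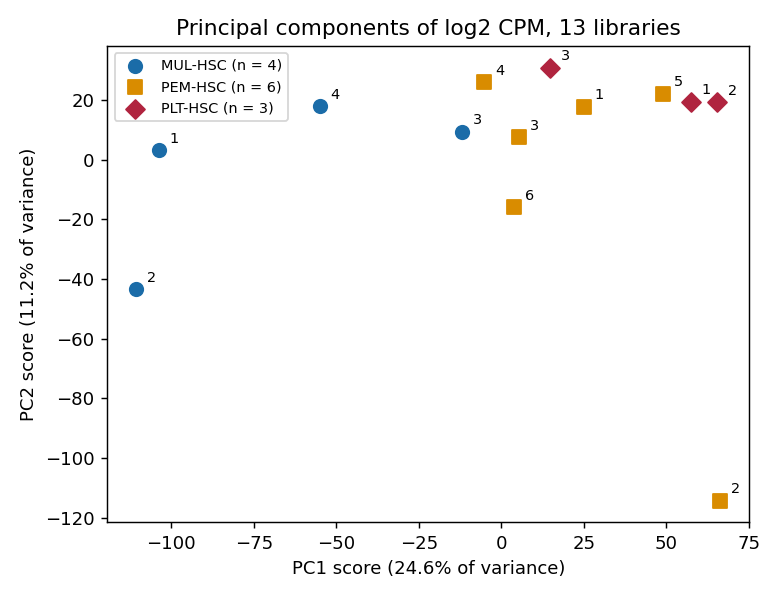
Scores of the 13 libraries on the first and second principal components of log2 CPM, with each library marked by its group and replicate number. The MUL-HSC libraries have the lowest PC1 scores, and MUL-HSC replicate 3, at -11.9, lies nearest to the other groups.

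The comparison of PLT-HSC with MUL-HSC asked which regions differ between HSCs of platelet-restricted and multilineage recipients. In PLT-HSC, 672 regions were more accessible and 759 less accessible, 1431 of 59408 tested, with median log2 fold changes of 1.57 and -1.51. The region with the smallest p lay on chromosome 18 from 12090062 to 12090577. It fell from 40.5 ± 9.09 CPM in MUL-HSC (SD, n = 4) to 4.48 ± 1.88 in PLT-HSC (SD, n = 3), a log2 fold change of -3.18 ± 0.31 (SE; adjusted p = 9.34e-06, edgeR quasi-likelihood test). PEM-HSC lay between them at 13.8 ± 4.67 CPM (SD, n = 6). On chromosome 8, the region from 124559257 to 124559832 had 105 counts over the 4 MUL-HSC libraries and 2 over the 3 PLT-HSC libraries, a ratio of 58.6 (95% counting interval 15.8 to 490). Its fitted log2 fold change of -5.63 became -8.02 without PLT-HSC replicate 3. On chromosome 6, the region from 113810669 to 113811399 fell from 10.9 ± 2.96 to 0.484 ± 0.168 CPM, a log2 fold change of -4.38 ± 0.54. Also lower were 2 regions of chromosome 12, from 116699023 to 116699739 (log2 fold change -2.90 ± 0.36) and from 116573099 to 116573523 (-3.26 ± 0.42).

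Of the regions higher in PLT-HSC, the one of smallest p lay on chromosome 7 from 130251625 to 130252345. It rose from 1.07 ± 1.06 CPM in MUL-HSC to 13.2 ± 4.16 CPM in PLT-HSC, a log2 fold change of 3.39 ± 0.44 (SE; adjusted p = 0.000113, edgeR quasi-likelihood test). A second region of chromosome 7, from 4449771 to 4450267, rose from 7.85 ± 0.716 to 26.1 ± 1.62 CPM (log2 fold change 1.71 ± 0.22). Higher too were regions on chromosome 15 from 81165385 to 81166025 (log2 fold change 3.53 ± 0.52), chromosome 16 from 41914285 to 41914919 (2.24 ± 0.33) and chromosome 3 from 100764778 to 100765709 (3.92 ± 0.57). The 4 MUL-HSC libraries held 5, 6 and 9 counts in the chromosome 3, chromosome 15 and first chromosome 7 regions. These fold changes therefore rest on few MUL-HSC counts. MUL-HSC replicate 3 held 4 of the 5 and 5 of the 9. Leaving out MUL-HSC replicate 3 moved the chromosome 3 log2 fold change to 5.52 and that of the first chromosome 7 region to 4.06. Thinning to the smallest total moved the log2 fold changes of the chromosome 8 and 6 regions to -7.00 and -3.41 and of the first chromosome 12 region to -3.96, and leaving out libraries under 2000000 counts moved that of chromosome 15 to 2.86. With 1 surrogate variable the chromosome 7 regions, in the order named, had log2 fold changes of 2.47 and 1.39. Those of chromosomes 15, 16 and 3 had 2.12, 2.13 and 2.43, that of chromosome 8 -4.39 and those of chromosome 12 -1.90 and -2.30. None of these stayed past the threshold, whereas the named regions of chromosomes 18 and 6 did. Values of PLT-HSC and MUL-HSC did not overlap in 1349 of the 1431 regions, and in 13.2% of all tested regions against 5.71% by chance. With 1 surrogate variable 4 regions passed, but that variable correlated at 0.995 in size with the first principal component and group membership accounted for 65.5% of its variance. The count was 559, 635 and 485 without MUL-HSC replicate 1, 2 or 4, and 350 and 609 without PLT-HSC replicate 1 or 2, 275 without the libraries under 2000000 counts and 846 with the library total as a covariate. The libraries under 2000000 counts were MUL-HSC replicates 1 and 2 and PEM-HSC replicates 2, 3 and 6. That fit thus kept only MUL-HSC replicates 3 and 4. The MUL-HSC libraries left out had the lowest PC1 scores, -104 and -111, so the fit cannot separate depth from the loss of these libraries. More regions were higher than lower without PLT-HSC replicate 1 (205 and 145), without PLT-HSC replicate 3 (1027 and 1007) after thinning to the smallest total (323 and 296) and with the share of counts in the 5000 strongest regions as a covariate (844 and 787).

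**Figure D2:**
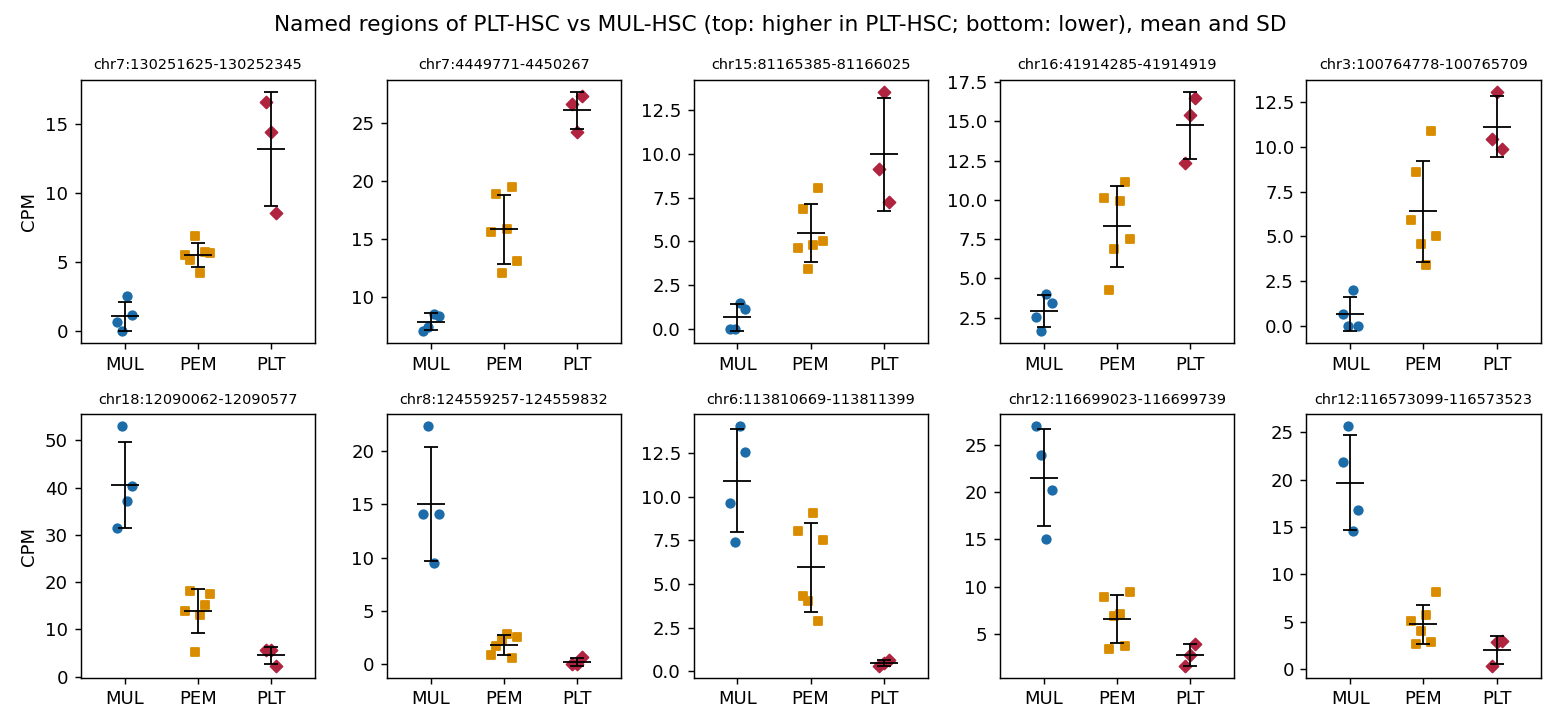
CPM of each library in the 10 regions named for PLT-HSC against MUL-HSC, with 1 panel per region (mm9), 1 point per library, and the group mean with its SD in black; the vertical axes differ between panels and do not all start at 0. For the chromosome 18 region the means are 40.5 CPM in MUL-HSC, 13.8 in PEM-HSC and 4.48 in PLT-HSC.

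The comparison of PEM-HSC with MUL-HSC gave 494 regions, 144 more and 350 less accessible in PEM-HSC, with median log2 fold changes of 1.47 and -1.31. The chromosome 8 region from 124559257 to 124559832 had the smallest p and fell from 15.0 ± 5.33 CPM (SD, n = 4) to 1.79 ± 0.919 (SD, n = 6), a log2 fold change of -3.04 ± 0.38 (SE; adjusted p = 0.000448, edgeR quasi-likelihood test). Regions on chromosome 18 from 76375444 to 76375896 (log2 fold change -3.45 ± 0.46), chromosome 8 from 36352052 to 36352578 (-2.87 ± 0.39), chromosome 2 from 148222720 to 148223841 (-1.37 ± 0.20) and chromosome 18 from 12090062 to 12090577 (-1.55 ± 0.22) were also lower. On chromosome 1, the region from 157230860 to 157231552 rose from 2.92 ± 1.03 to 12.3 ± 2.42 CPM (log2 fold change 1.99 ± 0.31) and the region from 15567743 to 15568330 rose from 2.15 ± 0.920 to 10.2 ± 3.86 CPM (2.25 ± 0.38), but thinning to the smallest total gave the second a log2 fold change of 1.43 (adjusted p = 0.166). Regions on chromosome 9 from 61162979 to 61164121 (log2 fold change 1.44 ± 0.25) and chromosome 12 from 31057494 to 31058601 (1.05 ± 0.18) were higher as well. The chromosome 9 region lost the threshold with the replicate number as a block (adjusted p = 0.0540, edgeR quasi-likelihood test). The chromosome 12 region lost it without MUL-HSC replicate 4 (0.0534, same test). Without the libraries under 2000000 counts both lost it (0.190 and 0.230, same test). The chromosome 4 region from 107547158 to 107547548 had 1 count over the MUL-HSC libraries and 93 over the PEM-HSC libraries, a ratio of 49.4 (95% counting interval 8.65 to 1972), and its fitted log2 fold change of 5.05 became 6.89 without MUL-HSC replicate 1 and 7.45 without the libraries under 2000000 counts. With 1 surrogate variable all named regions of this comparison lost the threshold. The chromosome 9 region then had a log2 fold change of 0.69 and the chromosome 8 regions, in the order named, -2.05 and -2.20. Leaving out the libraries under 2000000 counts ended 7 of the named calls. With 1 surrogate variable 1 region passed, and without the libraries under 2000000 counts 13 did, and 147 with the share of counts in the 5000 strongest regions as a covariate, where the balance turned to 82 higher and 65 lower. The count was 83, 83, 1215 and 61 without MUL-HSC replicate 1, 2, 3 or 4, and 180, 248, 777 and 166 without PEM-HSC replicate 1, 2, 4 or 5.

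PLT-HSC and PEM-HSC differed in 1 region past the threshold, on chromosome 6 from 113810669 to 113811399. It had 0.484 ± 0.168 CPM in PLT-HSC (SD, n = 3) and 5.96 ± 2.54 in PEM-HSC (SD, n = 6), a log2 fold change of -3.50 ± 0.55 (SE; adjusted p = 0.0299, edgeR quasi-likelihood test). The 3 PLT-HSC libraries held 4 counts there. At an unadjusted p under 0.05, 2739 regions passed, 4.61% of those tested. DESeq2 called 0 regions, and the count was 0 without PEM-HSC replicate 1, 4 or 6, MUL-HSC replicate 4 or PLT-HSC replicate 1 or 2, 4 without PEM-HSC replicate 3 and 11 without PLT-HSC replicate 3. The joint test of any difference among the 3 groups passed in 995 regions, and in 4 with 1 surrogate variable.

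Both comparisons with MUL-HSC called 115 regions higher and 220 lower, and 0 in opposite directions. Independent lists of these sizes would share 1.63 and 4.47, values that leave out the shared MUL-HSC libraries. Fold changes of the 2 comparisons correlated across regions (r = 0.803, covariance 0.184), where regions are not independent replicates. Simulated groups with no difference against the shared MUL-HSC libraries gave r = 0.555 and a covariance of 0.0516, a difference in covariance of 0.132. With separate MUL-HSC libraries for each comparison r was 0.388 to 0.485 over 6 splits, the mean covariance was 0.127, and 0 to 26 higher and 2 to 40 lower regions were shared, against at most 0.449 and 0.977 for independent lists. The lists then held 13 to 751 higher and 44 to 676 lower regions for PLT-HSC, and 0 to 303 and 3 to 365 for PEM-HSC.

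The groups are ordered by the lineages restored, and PEM-HSC was placed on a scale from 0 (MUL-HSC) to 1 (PLT-HSC) in libraries not used to pick the regions. Its median position was 0.822 (SD 0.128 over 36 overlapping splits, range 0.505 to 1.07), 0.774 for regions higher and 0.863 for regions lower in PLT-HSC. Single PEM-HSC libraries lay between 0.507 and 1.07, PLT-HSC libraries between 0.870 and 1.11, and MUL-HSC libraries between -0.105 and 0.267, the last being MUL-HSC replicate 3. The held-out MUL-HSC and PLT-HSC libraries themselves set the 0 and 1 of the scale, so their positions are centred there by construction. A PLT-HSC library held out alone has a position of 1 in that split. The spread of these groups therefore cannot be compared with that of PEM-HSC.

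**Figure D3:**
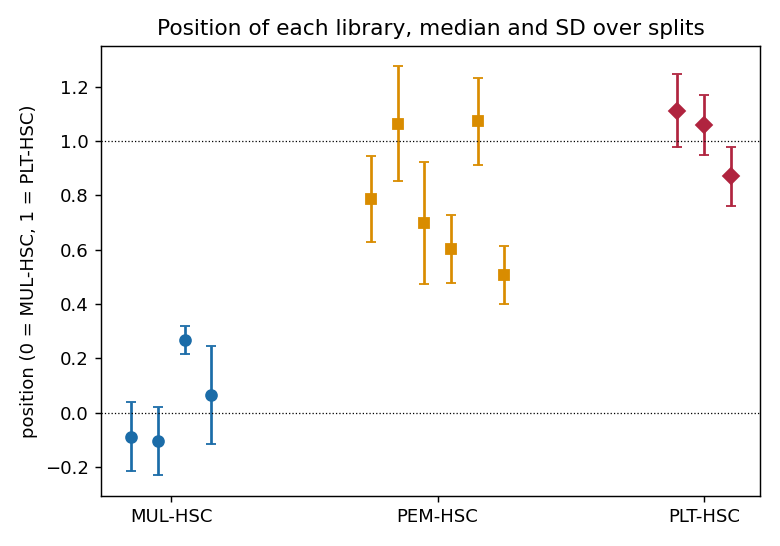
Position of each library between MUL-HSC (0) and PLT-HSC (1), as the median over the splits in which it was held out, with the SD over those splits. PEM-HSC libraries span 0.507 to 1.07 and overlap the PLT-HSC libraries at 0.870 to 1.11. Held-out MUL-HSC and PLT-HSC libraries set the 0 and 1 of the scale, so their positions are centred there by construction.

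Averaged over all pairs, libraries of the same group correlated more than libraries of different groups, by 0.0224 in mean Spearman rho (permutation p = 0.00757, one-sided). Mean rho was 0.861 within MUL-HSC, 0.865 within PEM-HSC and 0.877 within PLT-HSC. Between groups it was 0.820 for MUL-HSC with PLT-HSC, 0.835 for MUL-HSC with PEM-HSC and 0.870 for PEM-HSC with PLT-HSC, the last above the value within PEM-HSC. MUL-HSC replicate 3 had a mean rho of 0.853 with its own group, 0.865 with PEM-HSC and 0.854 with PLT-HSC. PEM-HSC replicates 1, 2, 4 and 5 also correlated more with PLT-HSC (0.883, 0.849, 0.882 and 0.897) than with their own group (0.880, 0.846, 0.877 and 0.877), and PLT-HSC replicate 3 more with PEM-HSC (0.878) than with its own (0.876). These correlations were not adjusted for depth. Library totals averaged 2013840 counts in MUL-HSC, 2536750 in PEM-HSC and 2995460 in PLT-HSC, and low counts lower a correlation. Depth may therefore underlie part of these orders, which was not tested.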

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

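The counts of other splits, and the tests of the chromosome 12 segment and of neighbouring regions in the part on other observations, the fits with a covariate and the regions chosen on fold change alone were chosen or had their bounds written only after the results were seen; the tests on library size and on signal over background were fixed before their results were seen.

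The difference between PLT-HSC and MUL-HSC was set against chance and 2 technical explanations. Only 1 of the 35 splits of the 7 libraries, the real one, gave as many as 1431 regions, so a chance split of these libraries is excluded at 0.05. The labels do not state that libraries came from separate recipients, so a chance difference between a few recipients is not excluded. The highest other split gave 915, with MUL-HSC replicate 3 placed with the PLT-HSC libraries. Library size within groups predicted 0.306% of the observed median fold change (-2.08% to 4.88% with each library left out in turn) and the share of counts in the 5000 strongest regions predicted -0.0164%, and in 4683 regions chosen on a log2 fold change of at least 1 whatever their p, and so not for a small spread, they predicted 1.20% (-2.60% to 7.38%) and -0.209% (-0.752% to 0.234%), so the tables argue against either as the whole source. With the share as a covariate the median log2 fold change of the 1431 regions, signed by direction, went from 1.54 to 1.53 and 1392 stayed past the threshold; with the total it also went to 1.53, but 694 lost the threshold, going from 1.37 to 1.33 while their median standard error rose from 0.353 to 0.387, and both fits use slopes in regions chosen partly for a small spread, which pulls such slopes towards 0. The lineage restored, and batches of sorting or sequencing that the labels do not give, stay open and untested.

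For PEM-HSC against MUL-HSC, 1 of 100 drawn splits, the real one, gave 494 regions and the highest other gave 35, and for any difference among the groups 1 of 100 gave 995 and the highest other 130. A chance split of these libraries is thus excluded at 0.05 for both, but a chance difference between a few recipients is not. With the share of counts in the 5000 strongest regions as a covariate 147 regions passed for PEM-HSC against MUL-HSC; the 383 of the 494 that lost the threshold went from a median log2 fold change, signed by direction, of 1.25 to 1.20 while their median standard error rose from 0.280 to 0.317. For PLT-HSC against PEM-HSC, 33 of 84 splits gave at least the 1 region seen and the highest other gave 74, so chance cannot be excluded. The 2 highest other splits, 74 with PEM-HSC replicates 2 and 6 and PLT-HSC replicate 2 set apart and 51 with PEM-HSC replicates 2, 3 and 6, point to a structure of the samples. These replicates had the smallest totals of the 9 libraries, 1276962, 1731365, 2378024 and 1958838 for PEM-HSC 2 and 6, PLT-HSC 2 and PEM-HSC 3, so library size may be a source, which was not tested.

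The chromosome 6 region from 113810669 to 113811399 passed between PLT-HSC and PEM-HSC (log2 fold change -3.50, adjusted p = 0.0299) but lost the threshold in 10 of 26 further fits, with log2 fold changes of -3.64 by DESeq2 (adjusted p 0.211), -3.28 without PLT-HSC replicate 1 (0.324) and -2.49 after thinning to the smallest total (0.976), and chance is not excluded for that comparison. PEM-HSC replicate 3 stood apart from its group in its TMM factor, 0.965 against 0.996 to 1.01, and in the share of counts in the 5000 strongest regions, 38.0% against 33.4% to 35.1%. MUL-HSC replicate 1 held the only count of its group at the chromosome 4 region from 107547158 to 107547548, 0.642 CPM against 0; any library with the sole count of its group stands apart in this way, so this value carries no weight. These were 3 of 46 groups of values tested, and chance alone marks about 1 in 20.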

How the results depend on the processing

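The strict filter, at a mean of 20 counts, gave 577 regions for PLT-HSC against MUL-HSC, 230 for PEM-HSC against MUL-HSC, 0 for PLT-HSC against PEM-HSC and 425 for any difference, with fewer regions tested. In the same order, 1 surrogate variable gave 4, 1, 1 and 4, thinning gave 619, 305, 0 and 484, leaving out libraries under 2000000 counts gave 275, 13, 4 and 131 with fewer samples, and the total as a covariate gave 846, 334, 1 and 540, and the share of counts in the 5000 strongest regions as a covariate gave 1631, 147 (82 higher, 65 lower), 2 and 860. These last 4 were chosen after seeing the data. For PLT-HSC against PEM-HSC, DESeq2, the fit of the compared groups alone and the fit without robust estimation gave 0 and no filter gave 4. Leaving out 1 library gave 350 to 2116, 61 to 1215, 0 to 11 and 192 to 1580 regions; for any difference it gave 328, 305 and 192 without MUL-HSC replicate 1, 2 or 4, 543 without PLT-HSC replicate 1 and 1580 without PLT-HSC replicate 3. Beyond the smaller tests and samples named, the cause was not tested. Counts for both comparisons with MUL-HSC stayed within 1.5 times under DESeq2, totals alone, loess offsets, no filter, the compared groups alone, no robust estimation and no X or Y. The regions called were not all the same. For PLT-HSC and PEM-HSC, DESeq2 kept 70.7% and 76.7% of the main calls and the compared groups alone 80.8% and 81.2%. No robust estimation kept 85.6% and 64.6%. The other settings of this list kept 82.6% to 99.4%. The replicate number as a block gave 683, 121, 9 and 475. Of 10 pairs with the same number, 0 correlated above 0.1, the highest at 0.099, and 2 of 20 best matches fell on the same number. No strong pairing by number was thus seen. A weaker pairing or a shared batch cannot be excluded in this way, and the labels state neither. The position was 0.774 and 0.736 with 50 and 500 regions per direction. The similarity difference ranged from 0.0164 to 0.0279 with 1 library left out (permutation p 0.00535 to 0.0333). The 21 named results had 553 further fits, of which 0 reversed and 38 lost the threshold. The surrogate variable ended 18 of the 21 calls, among them all those named for PEM-HSC against MUL-HSC. Leaving out libraries under 2000000 counts ended 7, all for PEM-HSC against MUL-HSC. Among these was its chromosome 8 region of smallest p, at a log2 fold change of -2.98 (adjusted p = 0.0711, edgeR quasi-likelihood test). The gene lists and motifs were not run. In the simulation, with 100 regions changed by each fold, 33% of 2-fold changes between PLT-HSC and MUL-HSC were recovered.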

Other observations

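The tests in this part were chosen after the values were seen. A segment of chromosome 12 from 116357715 to 117238558 held 32 tested regions, of which 19 were called lower in PLT-HSC than MUL-HSC and 10 lower in PEM-HSC. The 19 regions averaged 16.1 ± 4.62 CPM in MUL-HSC (SD, n = 4), 5.51 ± 2.18 in PEM-HSC (SD, n = 6) and 2.89 ± 1.38 in PLT-HSC (SD, n = 3). They were called in these same libraries, and the segment was picked as the largest cluster of such calls. The gap between PLT-HSC and MUL-HSC, and its contrast with the other regions, is thus in part set by that choice. PEM-HSC is set against the same MUL-HSC libraries. The other regions of the segment averaged 11.2 ± 0.417 CPM in MUL-HSC, 9.23 ± 1.32 in PEM-HSC and 6.94 ± 1.40 in PLT-HSC, and fitted values were lower than in MUL-HSC in 31 of the 32 regions for PLT-HSC and in 30 for PEM-HSC. The exception in PLT-HSC was the region from 116495786 to 116496549, with a log2 fold change of 0.43 ± 0.41. The regions from 116403614 to 116404548 (-0.24 ± 0.17) and from 116706171 to 116707147 (-0.56 ± 0.23) changed little, between neighbours at -1.79 and -1.80 and at -2.90 and -2.67. Genes in the segment were not identified, so a rearrangement of its DNA in blood cells was not examined.

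A change in the copy number of the segment was weighed first. The 8 regions of highest level had a median log2 fold change of -1.41 and the other 24 of -2.41, a gap that 11.4% of random sets reached, and this met the bound set for a copy number change. A second test, added after that result, argued against an equal change at all regions, in all cells or in some, since fold changes varied far more than their errors (Cochran Q = 244, 31 degrees of freedom). Loss of separate pieces of the segment, not tested, stays open, and a difference in accessibility between the groups, not tested separately, may also underlie the pattern.

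Called regions of PLT-HSC against MUL-HSC lay near each other, 19.8% having another of the same direction within 100 kb against 11.7% in 1000 random sets matched on level, whose maximum was 16.0%. Without the segment the share was 18.8%, above the random maximum of 15.7%, so random placement was excluded in both. A run is at least 4 called regions of the same direction, each within 200 kb of the next, and regions not called may lie between them. Among other runs, 5 called regions were higher on chromosome 9 from 58694738 to 58863575, where the median log2 fold change was 1.79 over called and 1.76 over all tested regions, and 5 on chromosome 1 from 15276289 to 15789704 (1.98 and 1.90). On chromosome 2 from 172996722 to 173203820, 5 were lower (-1.21 and -0.59). Runs of 4 called regions were higher on chromosome 1 from 191551129 to 191692287 (0.83 and 0.73) and lower on chromosome 11 from 119672311 to 120004544 (-1.99 and -0.28), chromosome 4 from 59251452 to 59433938 (-1.34 and 0.03) and chromosome 5 from 134997701 to 135088292 (-1.63 and -0.20). In the order named from chromosome 9 on, the runs spanned 7, 8, 17, 11, 36, 18 and 13 tested regions. Several of them thus held mostly regions that were not called.

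Among 5298 regions with a mean of at least 100 counts, the log count rose with the log library total at a median slope of 1.02. In 49 of them the slope was under 0.25, and 20 of these lay on chromosome 8 between 126062361 and 126148009. The region of chromosome 8 from 126116706 to 126117336 held 81 to 139 counts in all 13 libraries, whose totals differed 3.02-fold.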
